A study of Homo sapiens with 18 samples.

How the data were processed

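The series holds 8 RNA-seq libraries (untreated and 1, 3 and 6 h in NaCl, 2 each) and 10 Hi-C libraries (3 untreated, 3 after 1 h in NaCl, and 1 each for triptolide, NaCl with triptolide, NaCl with recovery, and NaCl with recovery and triptolide). Groups and batch numbers were taken from the sample labels. The ChIP-seq that the series design text mentions was not analysed here.

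Per the labels' protocols, RNA libraries were stranded and poly(A)-selected. The deposited RNA table holds raw read counts per Ensembl gene identifier, made by the authors with tools that the submitters' processing notes list as TopHat2 2.1.0, featureCounts 1.5.1 and DESeq2 1.14.1, on hg38. The annotation release and whether counting used strand are not given in the sources used here, so reads of overlapping genes on opposite strands may have been counted together. The deposited Hi-C files hold raw contact counts per pair of 50 kb bins, and only pairs within a chromosome, so the planned share of contacts between chromosomes could not be computed. All same-bin values are even (0 odd values over the 10 libraries), so each same-bin contact appears to be counted once per end, and these values were divided by 2. The authors also deposited 2 eigenvectors per chromosome at 100 kb, on no fixed unit, of which the first was used. The sign of each eigenvector and the matrix normalization behind it are not given in the sources used here, nor are the Hi-C aligner and read filters.

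RNA counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr on group) over all 8 libraries in 1 fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. Of 60554 identifiers 56558 matched a symbol, and identifiers without one took 0.146 to 0.219% of counts. With totals of 62918785 to 72779178 counts per library, data were simulated for the 1 h comparison over 22195 genes. They gave back 15 of 200 genes changed 1.25-fold, 102 of 200 changed 1.5-fold and 148 of 200 changed 2-fold. False calls numbered 0, 5 and 3. Libraries of 1 group differed beyond sampling noise, with a chi-square per degree of freedom of 2.91, 21.9, 7.07 and 16.6 for untreated, 1, 3 and 6 h. The single fit pools the spread over these groups and so treats as equal a noise that differed between them. Before the data were examined, 22 gene lists were fixed. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 63 tests. Of these, 22 passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.0758, 10 with an unadjusted p under 0.05). For the immediate-early list the estimated correlation was -0.0047, below the preset 0.01. A higher correlation therefore does not account for its lost call, and the 2 settings differ in more than the correlation used. For other lists the estimate lay far above the preset value. It was 0.72 for cytosolic ribosomal protein genes, 0.56 for mitochondrially encoded mRNAs and 0.29 for cohesin and CTCF machinery genes. The camera p-values of these 3 lists with the preset correlation can therefore be much too low. The fry test, which asks whether a list's genes move 1 way and does not compare them with other genes, called 30. In simulated data, 6 of 6 raised lists were called with either correlation, with 0 false calls.

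Genes named in the text were chosen by a rule fixed beforehand. For each comparison with untreated cells, these are the 6 largest increases and 6 largest decreases among genes past the threshold, with a mean log2 CPM of at least 2 and the same direction in both batches. Of each list, up to 3 called members with the lowest p are named, or the 1 member with the lowest p where none passed. Some genes that this rule selects are not reported here. For Hi-C, they are the 3 runs of adjacent bins and the 3 boundaries with the largest change each way among those past the threshold.

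Hi-C matrices were balanced by 60 rounds of iterative correction after bins under 25% of the median coverage were left out. Insulation was measured with a 500 kb diamond, and boundaries were minima with a strength of at least 0.25 over flanks of 500 kb in the summed untreated libraries. Boundary criteria, masking and the rule that orients each eigenvector by its correlation with gene density were set after the files had been seen. Compartment strength is (AA + BB) / (AB + BA) of contacts over expected between the 20% highest and 20% lowest bins of the mean untreated eigenvector. Single values were compared by two-sided exact permutation of 3 against 3 libraries (20 assignments, smallest p 0.1), and by sign flips of the batch differences (8 flips, smallest p 0.25). Eigenvectors, scaled to unit SD, and insulation scores were tested with limma, and contacts summed into 1 Mb bin pairs with a mean of at least 20 with edgeR, scaled to their total. In simulated matrices 32 of 32 planted boundaries were found at either of 2 strengths and 0 where none was planted, and planted compartment strengths of 1, 2 and 4 were measured as 0.998, 1.98 and 3.94. The first version of the compartment simulation confounded compartments with domains and was redesigned, with the measuring functions left as they were. In simulated changes of 200 items, limma found 0 eigenvector bins changed by 0.5 SD units and 135 changed by 1, and 104 boundaries changed by 0.25 and 179 changed by 0.5. For bin pairs edgeR found 0 changed by 0.5 and 112 changed by 1 on the log2 scale. False calls numbered 5 with bins changed by 1, 5 and 9 for boundaries, and 8 with pairs changed by 1. Far fewer items changed in these simulations than were called in the data, and recovery after Benjamini-Hochberg adjustment depends on that share. The simulations therefore do not give the share found in the data.

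The batch number pairs the samples, since the labels give it as a shared batch. Deviations of same-batch Hi-C libraries from their group means correlated at 0.33, 0.26 and 0.23 for batches 1, 2 and 3, against -0.066 to -0.23 across batches. Deviations from a group mean cancel within the group, so positive same-batch values bring negative ones across batches partly by arithmetic. For RNA the correlation of batch deviations lay between -0.016 and 0.080, so no shared batch deviation was seen there.

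Genes were placed in Hi-C bins by their midpoint, in place of the planned promoter bin, because the reference gene table gives no strand. Placement used the current symbol and then a synonym carried by only 1 reference gene. Synonyms were added after the results with current symbols had been seen, because under 80% of all tested genes had been placed, and the share was checked per set of genes later still. With current symbols alone, 84.8% of higher, 73.4% of lower and 80.1% of uncalled genes were placed. In simulated null data the permutation test gave p under 0.05 in 10 of 200 draws, and in 199 of 200 with a shift of 1 SD. Gene positions are from a RefSeq table of GRCh38, the build the files use.

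Alternatives fixed beforehand were the batch as a block, other scalings, DESeq2 1.42.0, other filters, fold thresholds, windows, distance limits and quantiles, and leaving out each library. Others, named in the closing section, were added after seeing the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.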

Results

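T47D cells, a human luminal breast cancer line that expresses the estrogen and progesterone receptors, were deprived of steroids in medium with 10% charcoal-stripped serum for 48 h and then of serum overnight. NaCl was then added to the medium, which raises its osmolarity. The sample labels give 110 mM NaCl and the series design text gives 100 mM. Polyadenylated RNA was sequenced from untreated cells and after 1, 3 and 6 h in NaCl, with 2 libraries per group. In situ Hi-C, which counts ligations between DNA segments that lie close together in the nucleus, was performed on 3 untreated and 3 NaCl-treated (1 h) libraries. Single Hi-C libraries covered 4 further conditions with triptolide, an inhibitor of transcription initiation, with recovery in isotonic medium, or with both. The RNA libraries held 62918785 to 72779178 counts over 60554 gene identifiers, of which 22195 were tested. The Hi-C libraries held 65712963 to 142395486 contacts within chromosomes. Nothing in the labels says that libraries of one group came from separate cultures, beyond a batch number. The p-values therefore measure the spread between these libraries, which may be technical. For RNA that spread is pooled over the 4 groups, although replicate noise differed between them. RNA levels below are CPM, counts scaled to an equal TMM-adjusted library size, as mean ± SD of 2 libraries, and positions are on GRCh38. Such levels are relative to the other genes of a library, so a change in total RNA per cell would not be seen.

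The first comparison asked which transcripts differed after 1 h in NaCl. The AP-1 transcription factor genes FOSB (ENSG00000125740, chromosome 19, 45467996 to 45475179) and FOS (ENSG00000170345, chromosome 14, 75278828 to 75282230) were among the largest increases. FOSB rose from 2.3 ± 0.216 to 15.6 ± 0.174 CPM, a log2 fold change of 2.76 (SE 0.11, adjusted p = 1.37e-10), and FOS rose from 3.53 ± 0.186 to 22.8 ± 1.47 CPM, a log2 fold change of 2.69 (SE 0.11, adjusted p = 1.37e-10). SNAI1, which encodes a zinc finger repressor of epithelial genes (ENSG00000124216, chromosome 20, 49982980 to 49988886), rose from 0.422 ± 0.118 to 2.74 ± 0.687 CPM, a log2 fold change of 2.69. The MAP kinase phosphatase gene DUSP1, SERPINA10 and EGR1 followed, with log2 fold changes of 2.05, 1.92 and 1.77. The largest decrease was that of the long noncoding RNA NEAT1 (ENSG00000245532, chromosome 11, 65422798 to 65445540). It went from 372 ± 4.89 to 73.4 ± 1.23 CPM, a log2 fold change of -2.34 (SE 0.11, adjusted p = 1.57e-09). These are counts per gene in poly(A)-selected libraries, so isoforms of NEAT1 are not told apart and RNA without a poly(A) tail is largely missed. The other named decreases were also mostly noncoding transcripts or identifiers without a symbol. MIR34AHG, a microRNA host transcript (ENSG00000228526, chromosome 1, 9148011 to 9182338), fell from 12.4 ± 0.127 to 3.03 ± 0.0367 CPM, and LINC01089 fell from 8.69 ± 0.368 to 2.92 ± 0.0906 CPM. The identifiers ENSG00000188206 and ENSG00000260261 had log2 fold changes of -2.12 and -1.91, and ENSG00000279088 one of -1.61.

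Among the gene lists fixed beforehand, the immediate-early genes had the largest median change at 1 h. Of these, 18 of the 37 tested members rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 fold change of 0.37 (camera adjusted p = 7.60e-08, and adjusted p = 0.0758 with an estimated correlation). Of the heat shock genes driven by HSF1, 7 of the 20 tested members rose and 0 fell (8 and 0 adjusted over the list alone) (camera adjusted p = 8.95e-06, and adjusted p = 0.131 with an estimated correlation). HSPA8, the constitutive cytosolic chaperone, rose from 735 ± 43.6 to 1493 ± 4.96 CPM, and the stress-inducible HSPA1B and HSPA1A had log2 fold changes of 1.10 and 1.03. Reads of these last 2 near-identical genes could have been split between them, so their separate values are uncertain. Of the short-lived transcription regulators, 9 of the 19 tested members rose and 2 fell (10 and 2 adjusted over the list alone) (camera adjusted p = 0.00592, and adjusted p = 0.407 with an estimated correlation). HES1 rose from 26.8 ± 0.70 to 65.8 ± 1.51 CPM, BCL6 from 114 ± 1.64 to 166 ± 8.05 CPM and ID2 from 10.3 ± 0.931 to 16.5 ± 0.506 CPM. The cytosolic ribosomal protein genes had a median of 0.10 (camera adjusted p = 0.00141, and adjusted p = 0.933 with an estimated correlation), although 2 of the 76 tested members rose and 0 fell (0 and 0 adjusted over the list alone). RPL12 and RPS2 were the members that passed over all genes. For the replication-dependent histone genes, 1 of the 13 tested members rose and 0 fell (2 and 0 adjusted over the list alone) (camera adjusted p = 0.0451, and adjusted p = 0.504 with an estimated correlation, and 0.0544 with the batch as a block). That member was H2AC6, from 122 ± 4.3 to 145 ± 0.972 CPM. Messages of this class mostly lack a poly(A) tail, and the libraries were poly(A)-selected.

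No other list passed camera at 1 h. Of the osmoprotective genes, 2 of the 15 tested members rose and 2 fell (2 and 3 adjusted over the list alone). SLC38A2, a neutral amino acid transporter gene, rose from 394 ± 6.46 to 897 ± 136 CPM, while the amino acid transporter gene SLC7A5 fell from 950.5 ± 23.1 to 766 ± 21.5 CPM. In the integrated stress response list, 3 of the 20 tested members rose and 2 fell (3 and 2 adjusted over the list alone). PPP1R15A, a phosphatase subunit gene, rose from 26.7 ± 1.23 to 48.7 ± 0.271 CPM, whereas CHAC1, a glutathione-degrading enzyme gene, fell from 32 ± 1.15 to 17.4 ± 3.25 CPM and DDIT4 fell from 203 ± 13.5 to 157 ± 14.9 CPM. In the other lists few members passed. The numbers that rose and fell were 3 and 2 of 20 luminal and estrogen receptor genes, 0 and 2 of 20 G2/M genes, 0 and 1 of 20 G1/S genes, 1 and 2 of 18 p53 targets and 1 and 2 of 11 NF-kB and inflammatory genes. They were 2 and 3 of 18 cohesin and CTCF machinery genes, 2 and 1 of 24 RNA polymerase II elongation genes, 1 and 2 of 21 ion and volume transport genes, 0 and 1 of 15 unfolded protein response genes and 1 and 0 of 16 glycolysis and hypoxia genes. Adjusted over the list alone, these differed only for the NF-kB (1 and 3) and cohesin (3 and 3) lists. NFKBIA, the gene of an NF-kB inhibitor, rose from 64.1 ± 0.119 to 113 ± 1.71 CPM, and IRF1 and TNFAIP3 had log2 fold changes of -0.50 and -0.65. In the p53 list PLK2 rose by 0.36 on the log2 scale, and TP53INP1 and AEN had values of -0.73 and -0.50. MKI67, a proliferation marker gene, fell from 116 ± 1.86 to 63.3 ± 6.76 CPM, and CENPF and CCNE1, the other called members of the G2/M and G1/S lists, had log2 fold changes of -0.35 and -0.51. Among genes of the transcription and cohesin machinery, AFF4, PDS5A and YY1 had log2 fold changes of -0.73, -0.47 and -0.38. HEXIM1, CDK7 and ESCO1 had values of 0.35, 0.32 and 0.45. Of the luminal genes, MYB, SPDEF and GATA3 were the 3 that rose, with log2 fold changes of 0.70, 0.34 and 0.30. ADM, EDEM1, WNK1 and SGK1 had log2 fold changes of 0.41, -0.54, -0.33 and 1.67, SGK1 at under 1 CPM. MSMO1, MT-CYB and THY1 did not pass, with values of 0.24, 0.19 and -0.35; with the batch as a block, MSMO1 passed. Among markers of other cell types, the basal markers MYLK and EGFR fell by 0.53 and 0.50, and the monocyte marker CD14 rose from 0.163 ± 0.0588 to 0.701 ± 0.101 CPM.

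By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1281 genes were higher and 1593 lower at 1 h. The count fell to 1386 without untreated replicate 1 and to 1434 without untreated replicate 2. The balance turned without NaCl 1 h replicate 1 (1389 higher, 1139 lower) and with DESeq2's Wald test (1194 higher, 1161 lower).

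**Figure D1:**
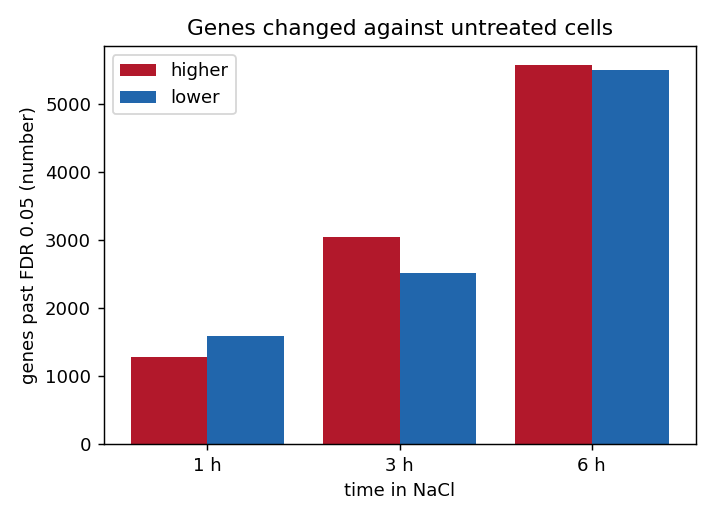
Number of genes (vertical axis) with an adjusted p under 0.05 by edgeR's quasi-likelihood test after 1, 3 and 6 h in NaCl (horizontal axis), each against untreated cells with 2 libraries per group. Red bars are genes higher in NaCl (1281, 3048 and 5572) and blue bars genes lower in NaCl (1593, 2513 and 5499).

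The second comparison set 3 h in NaCl against untreated cells. SNAI1 rose from 0.422 ± 0.118 to 18.7 ± 1.82 CPM, a log2 fold change of 5.47 (SE 0.19, adjusted p = 4.39e-12), and FOSB rose from 2.3 ± 0.216 to 63.6 ± 3.12 CPM, a log2 fold change of 4.79 (SE 0.11, adjusted p = 6.16e-14). OVOL1, a zinc finger transcription factor gene (ENSG00000172818, chromosome 11, 65787063 to 65797214), rose from 6.1 ± 1.07 to 91.5 ± 3.83 CPM. SLC38A2 (ENSG00000134294, chromosome 12, 46358188 to 46372773) rose from 394 ± 6.46 to 4655 ± 251 CPM, a log2 fold change of 3.56 (SE 0.10, adjusted p = 6.74e-13). HBEGF, the gene of a growth factor of the EGF family, rose from 2.82 ± 0.146 to 29.6 ± 2.33 CPM, and the identifier ENSG00000256304 rose from 1.35 ± 0.27 to 22.1 ± 0.315 CPM. The largest decrease was in the zinc finger gene ZNF14 (ENSG00000105708, chromosome 19, 19710472 to 19733112), from 13.9 ± 0.864 to 1.46 ± 0.0568 CPM, a log2 fold change of -3.25 (SE 0.13, adjusted p = 2.95e-11). CHAC1 fell from 32 ± 1.15 to 4.02 ± 0.374 CPM and NEAT1 from 372 ± 4.89 to 57.5 ± 1.84 CPM. ZBTB3, ZNF737 and MIR34AHG had log2 fold changes of -2.57, -2.56 and -2.50.

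Of the immediate-early genes, 25 of the 37 tested members rose and 5 fell (27 and 5 adjusted over the list alone), with a median log2 fold change of 1.24 (camera adjusted p = 1.40e-10, and adjusted p = 0.0758 with an estimated correlation). The phosphatase genes DUSP1 and DUSP10 rose from 7.97 ± 0.00249 to 83.4 ± 0.451 CPM and from 10.8 ± 0.268 to 80.7 ± 2.18 CPM. Of the heat shock genes, 14 of the 20 tested members rose and 0 fell (14 and 0 adjusted over the list alone) (camera adjusted p = 3.14e-08, and adjusted p = 0.0958 with an estimated correlation). The member with the lowest p was the cochaperone gene DNAJA1, which rose from 97.9 ± 0.795 to 504 ± 24.9 CPM. HSPA1B and HSPA1A had log2 fold changes of 2.80 and 2.44. Of the osmoprotective genes, 6 of the 15 tested members rose and 0 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.00594, and adjusted p = 0.286 with an estimated correlation). SLC6A6, the taurine transporter gene, rose from 74.5 ± 2.54 to 144 ± 3.9 CPM. Of the cholesterol biosynthesis genes, 8 of the 19 tested members rose and 0 fell (8 and 0 adjusted over the list alone) (camera adjusted p = 0.00197, and adjusted p = 0.271 with an estimated correlation). INSIG1 rose from 142 ± 0.806 to 293 ± 15.2 CPM and SC5D from 204 ± 0.222 to 459.6 ± 27.3 CPM. Of the cohesin and CTCF machinery genes, 4 of the 18 tested members rose and 0 fell (4 and 0 adjusted over the list alone) (camera adjusted p = 0.0284, and adjusted p = 0.773 with an estimated correlation), with log2 fold changes of 0.42 for ZNF143, 0.37 for the cohesin release factor gene WAPL and 0.34 for STAG1. Of the ion and volume transport genes, 6 of the 21 tested members rose and 1 fell (6 and 1 adjusted over the list alone) (camera adjusted p = 0.0308, and adjusted p = 0.286 with an estimated correlation). The kinase gene SGK1 rose from 0.232 ± 0.0784 to 5.13 ± 1.12 CPM, ATP1B3, a sodium pump subunit gene, rose from 110.3 ± 0.71 to 181 ± 5.23 CPM, and LRRC8C rose from 0.741 ± 0.0626 to 1.67 ± 0.22 CPM. Of the short-lived regulators, 9 of the 19 tested members rose and 5 fell (10 and 5 adjusted over the list alone) (camera adjusted p = 0.0451, and adjusted p = 0.62 with an estimated correlation, and 0.0527 with the batch as a block). BCL6 rose from 114 ± 1.64 to 488 ± 15.3 CPM and TSC22D3 from 73.6 ± 0.227 to 227 ± 7.35 CPM, and HES1 had a log2 fold change of 1.13.

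The mitochondrially encoded mRNAs were the only list that camera called lower at 1, 3 or 6 h. At 3 h, 0 of the 13 tested members rose and 11 fell (0 and 12 adjusted over the list alone) (camera adjusted p = 2.99e-04, and adjusted p = 0.666 with an estimated correlation). MT-ND5 fell from 3184 ± 125 to 1846 ± 107 CPM, MT-ND1 from 1367 ± 63.2 to 914 ± 93.6 CPM and MT-ND4 from 6467 ± 222 to 4981 ± 178 CPM, all subunits of respiratory complex I. No further list passed camera at 3 h. The numbers that rose and fell were 6 and 4 of 20 integrated stress response genes, 2 and 3 of 11 NF-kB and inflammatory genes, 4 and 2 of 18 p53 targets, 3 and 2 of 20 luminal and estrogen receptor genes and 1 and 3 of 16 glycolysis and hypoxia genes. They were 3 and 6 of 24 RNA polymerase II elongation genes, 3 and 0 of 20 G1/S genes, 1 and 1 of 15 unfolded protein response genes, 2 and 0 of 13 histone genes and 1 and 1 of 76 cytosolic ribosomal protein genes. Adjusted over the list alone, these differed only for the integrated stress response (6 and 6), NF-kB (4 and 3), glycolysis and hypoxia (1 and 4) and ribosomal protein (0 and 0) lists. PPP1R15A rose from 26.7 ± 1.23 to 154 ± 1.23 CPM, while DDIT4 fell from 203 ± 13.5 to 61.8 ± 2.66 CPM. NFKBIA rose from 64.1 ± 0.119 to 350.4 ± 2.93 CPM, and IRF1 and LIF had log2 fold changes of -0.67 and -1.53. The cell cycle inhibitor gene CDKN1A rose from 191 ± 2.58 to 323 ± 5.07 CPM, and TP53INP1 and AEN had values of -0.79 and -0.55. For the p53 list as a whole the median (-0.015) and mean (0.20) differed in sign. ADM, a vasodilator peptide gene of the hypoxia list, rose from 12.5 ± 0.536 to 38.4 ± 0.581 CPM, and ANKRD37 and PFKFB3 had log2 fold changes of -0.71 and -0.30. HEXIM1 and CDK13 rose by 0.82 and 0.67 on the log2 scale, and CCNT1, the gene of a P-TEFb cyclin, fell from 95.2 ± 1.52 to 54 ± 0.286 CPM. ESR1, the estrogen receptor gene, rose from 171 ± 3.12 to 212 ± 1.84 CPM, and ERBB3 had a log2 fold change of -0.28. DNAJB9, XBP1, SLBP, CDC25A and PCNA had values of 0.58, -0.27, 0.33, 0.34 and 0.27. RPS2 and RPSA had values of 0.41 and -0.41, and the histone gene H1-2 one of 0.33. A call for H4C3, at 0.145 CPM in NaCl, was lost with DESeq2. CDK1 and VIM did not pass, with log2 fold changes of 0.23 and -0.16; with the batch as a block, CDK1 passed. CD14 rose from 0.163 ± 0.0588 to 3.01 ± 0.0303 CPM.

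At 3 h, 3048 genes were higher and 2513 lower by the same test. The count fell to 3606 and 3542 without untreated replicate 1 or 2, and to 3563 and 3689 without NaCl 3 h replicate 1 or 2.

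The third comparison set 6 h in NaCl against untreated cells. SNAI1 again had the largest increase, from 0.422 ± 0.118 to 23.5 ± 0.985 CPM, a log2 fold change of 5.79 (SE 0.19, adjusted p = 8.71e-13). S1PR3, a sphingosine phosphate receptor gene (ENSG00000213694, chromosome 9, 88990863 to 89005155), rose from 3.88 ± 0.0234 to 111 ± 8.32 CPM, a log2 fold change of 4.83 (SE 0.10, adjusted p = 1.48e-14). HSPA1B (ENSG00000204388, chromosome 6, 31827738 to 31830254) rose from 52 ± 5.54 to 1181 ± 18.9 CPM and HSPA1A (ENSG00000204389, chromosome 6, 31815543 to 31817942) from 68.9 ± 8.55 to 1242 ± 1.69 CPM. SLC5A3, the gene of a transporter of the osmolyte myo-inositol (ENSG00000198743, chromosome 21, 34073578 to 34106260), rose from 30.7 ± 0.382 to 586 ± 53.6 CPM, a log2 fold change of 4.25 (SE 0.13, adjusted p = 4.67e-13). TENT5C, a poly(A) polymerase gene, rose from 4.45 ± 0.413 to 64.9 ± 5.12 CPM. The largest decrease was that of the MAP kinase phosphatase gene DUSP4 (ENSG00000120875, chromosome 8, 29333064 to 29350684), from 80.8 ± 5.08 to 6.88 ± 0.383 CPM, a log2 fold change of -3.55 (SE 0.10, adjusted p = 1.34e-13). ZNF551, ARHGAP40, ZNF608 and TIGD2 fell, with log2 fold changes of -2.73, -2.58, -2.58 and -2.53, and ENSG00000262823 fell from 13.4 ± 0.624 to 1.54 ± 0.37 CPM.

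Of the osmoprotective genes, 10 of the 15 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.90 (camera adjusted p = 4.82e-04, and adjusted p = 0.205 with an estimated correlation). SLC38A2 was at 2355 ± 181 CPM. Of the heat shock genes, 19 of the 20 tested members rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 4.19e-10, and adjusted p = 0.0849 with an estimated correlation). DNAJA1 rose from 97.9 ± 0.795 to 852 ± 17.1 CPM. Of the immediate-early genes, 23 of the 37 tested members rose and 9 fell (23 and 9 adjusted over the list alone) (camera adjusted p = 7.99e-04, and adjusted p = 0.131 with an estimated correlation), with FOSB at 26.4 ± 1.19 and DUSP1 at 57.6 ± 0.374 CPM. Of the cholesterol biosynthesis genes, 14 of the 19 tested members rose and 2 fell (14 and 3 adjusted over the list alone) (camera adjusted p = 2.46e-04, and adjusted p = 0.205 with an estimated correlation). SC5D and MSMO1, which encode sterol-modifying enzymes, rose from 204 ± 0.222 to 909 ± 83.4 CPM and from 137 ± 1.72 to 437 ± 58.7 CPM, and INSIG1 had a log2 fold change of 1.12. Of the ion and volume transport genes, 11 of the 21 tested members rose and 2 fell (11 and 2 adjusted over the list alone) (camera adjusted p = 0.00927, and adjusted p = 0.242 with an estimated correlation). The sodium pump subunit genes ATP1B1 and ATP1B3 rose from 168 ± 2.45 to 943 ± 24.1 CPM and from 110.3 ± 0.71 to 430.0 ± 13.5 CPM, and the potassium channel gene KCNK5 from 3.01 ± 0.27 to 18.6 ± 1.15 CPM. Of the cytosolic ribosomal protein genes, 61 of the 76 tested members rose and 0 fell (70 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 7.67e-08, and adjusted p = 0.832 with an estimated correlation). RPS2, RPL7A and RPL18 had log2 fold changes of 0.88, 0.66 and 0.58. Many genes of this class have processed pseudogenes that can take their reads.

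Of the cohesin and CTCF machinery genes, 9 of the 18 tested members rose and 0 fell (10 and 0 adjusted over the list alone) (camera adjusted p = 0.0134, and adjusted p = 0.702 with an estimated correlation). ZNF143 rose from 18 ± 1.45 to 45.4 ± 1.01 CPM, YY1 from 167 ± 1.61 to 313 ± 20.7 CPM and CTCF, the insulator protein gene, from 105 ± 2.57 to 188 ± 3.29 CPM. Of the RNA polymerase II elongation genes, 13 of the 24 tested members rose and 3 fell (13 and 4 adjusted over the list alone) (camera adjusted p = 0.0451, and adjusted p = 0.447 with an estimated correlation, and 0.0524 with the batch as a block). HEXIM1 rose from 157 ± 1.05 to 384 ± 58.6 CPM and CDK13 from 82.3 ± 2.81 to 132 ± 1.88 CPM. Of the short-lived regulators, 12 of the 19 tested members rose and 4 fell (12 and 4 adjusted over the list alone) (camera adjusted p = 0.00239, and adjusted p = 0.357 with an estimated correlation). TSC22D3 rose from 73.6 ± 0.227 to 550.4 ± 5.14 CPM, and BCL6 and BCL3 rose, with log2 fold changes of 1.65 and 2.07. No further list passed camera at 6 h. Of the glycolysis and hypoxia genes, 9 of the 16 tested members rose and 3 fell (9 and 3 adjusted over the list alone), with ADM rising from 12.5 ± 0.536 to 99.4 ± 1.9 CPM and ENO1 and ALDOA at 0.70 and 0.49 on the log2 scale. Of the histone genes, 5 of the 13 tested members rose and 1 fell (5 and 1 adjusted over the list alone), and H1-2, H2BC5 and H1-3 had log2 fold changes of 1.10, 0.71 and 2.33. Of the mitochondrially encoded mRNAs, 0 of the 13 tested members rose and 4 fell (0 and 4 adjusted over the list alone), and MT-ND5, MT-ND4 and MT-ND1 had values of -0.77, -0.32 and -0.30.

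Of the integrated stress response genes, 9 of the 20 tested members rose and 7 fell (9 and 7 adjusted over the list alone), and DDIT3, PPP1R15A and CHAC1 had log2 fold changes of -1.28, 0.93 and -1.33. The list's median was 0.064 and its mean -0.050. Of the unfolded protein response genes, 4 of the 15 tested members rose and 1 fell (3 and 1 adjusted over the list alone), with DNAJB9, XBP1 and HSPA5 at 1.42, -0.69 and 0.33. Of the p53 targets, 6 of the 18 tested members rose and 6 fell (6 and 6 adjusted over the list alone), with log2 fold changes of -0.64 and -0.79 for AEN and SESN1, and GADD45A going from 4.37 ± 0.386 to 2.19 ± 0.212 CPM. Of the NF-kB and inflammatory genes, 3 of the 11 tested members rose and 4 fell (3 and 4 adjusted over the list alone). NFKBIA rose from 64.1 ± 0.119 to 603 ± 22.3 CPM and NFKB1 from 30.7 ± 1.01 to 63.2 ± 2.57 CPM, while TNFAIP3 fell from 5.37 ± 0.206 to 1.92 ± 0.413 CPM. Of the luminal and estrogen receptor genes, 7 of the 20 tested members rose and 7 fell (7 and 8 adjusted over the list alone). GATA3, a luminal transcription factor gene, rose from 685 ± 18.6 to 1359.8 ± 96.1 CPM, while KRT19 fell from 3699 ± 66.2 to 1858 ± 24.9 CPM and ERBB3 from 757 ± 15.8 to 409 ± 25 CPM. Of the G2/M genes, 9 of the 20 tested members rose and 2 fell (9 and 2 adjusted over the list alone), with CCNB2, PLK1 and CDC20 at -0.52, 0.46 and 0.46. Of the G1/S genes, 6 of the 20 tested members rose and 5 fell (6 and 5 adjusted over the list alone), with SLBP, CDC25A and E2F2 at 0.94, 0.89 and 0.56. Among markers of other cell types, 0 of 6 tested basal markers rose and 2 fell, 1 of 5 fibroblast markers rose, and 2 of 4 immune markers rose, the last list too short for camera. EGFR and MYLK had values of -0.49 and -0.47, and CD14 rose from 0.163 ± 0.0588 to 2.63 ± 0.127 CPM. Calls for the fibroblast marker DCN (from 0.748 ± 0.168 to 1.2 ± 0.144 CPM) and the myeloid marker LYZ (from 0.462 ± 0.0933 to 0.765 ± 0.231 CPM) were lost with DESeq2.

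At 6 h, 5572 genes were higher and 5499 lower. This near-even balance turned with DESeq2 size factors (5522 higher, 5544 lower), with DESeq2's Wald test (4587 and 4852) and without untreated replicate 1 (4189 and 4341) or 2 (4127 and 4350). It turned too without NaCl 3 h replicate 1 (5322 and 5423) or 2 (5347 and 5400) and without NaCl 6 h replicate 1 (5075 and 5111) or 2 (5036 and 5170). Among changes of at least 2-fold, 2208 genes were higher and 1413 lower. TMM scaling holds the typical change near 0, and the median log2 fold change at 6 h was 0.016. A near-even balance over all called genes is therefore partly set by the scaling.

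**Figure D2:**
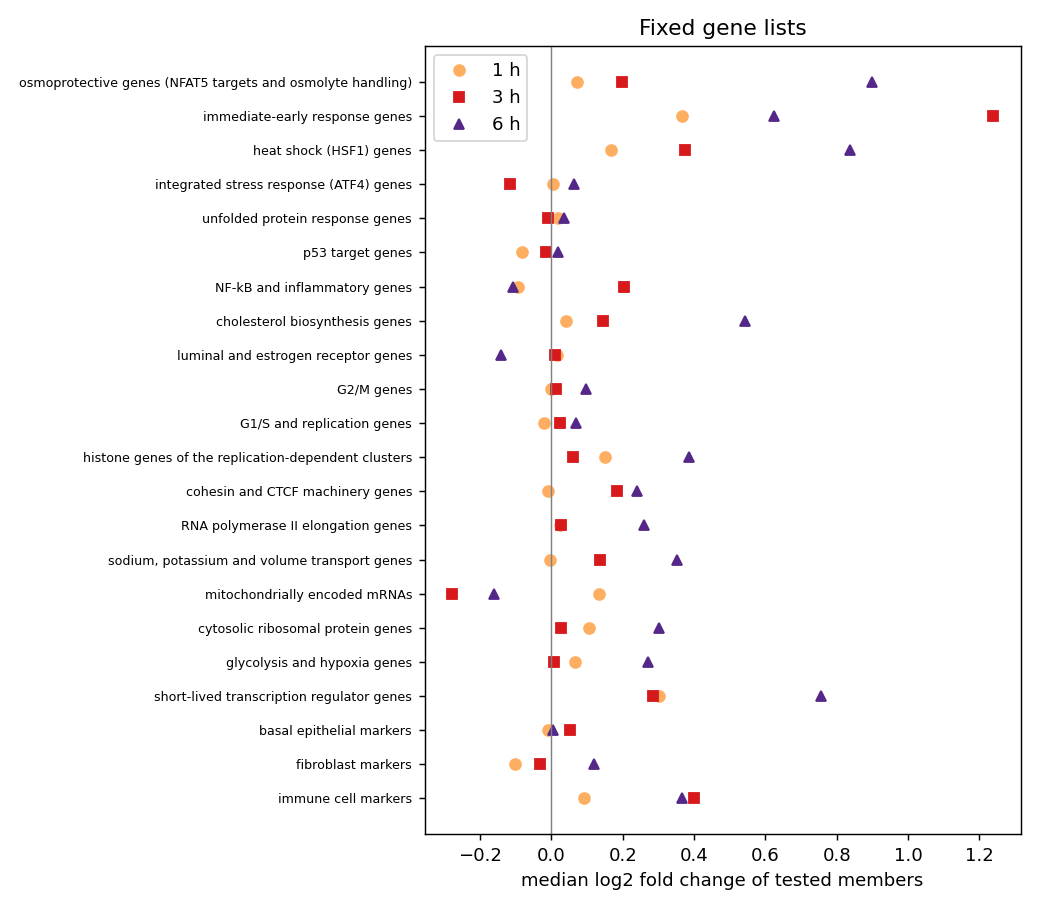
Median log2 fold change against untreated cells (horizontal axis) over the tested members of each of the 22 gene lists (vertical axis) after 1 h (circles), 3 h (squares) and 6 h (triangles) in NaCl. The immediate-early genes had their largest median at 3 h (1.24), and the osmoprotective and heat shock genes at 6 h (0.90 and 0.84).

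Successive times were also compared directly. From 1 to 3 h, 2489 genes rose and 1558 fell; the total was 2448 without NaCl 3 h replicate 1 and 2638 without replicate 2. From 3 to 6 h, 4323 genes rose and 4707 fell, a balance that turned among changes of at least 2-fold (1257 and 878). Between 1 and 3 h the immediate-early genes rose by a median of 0.62 on the log2 scale, and between 3 and 6 h they fell by 0.53 (camera adjusted p = 3.97e-08 and 0.00265, and 0.0917 and 0.15 with an estimated correlation). DDIT4 rose by 1.96 (SE 0.084, adjusted p = 6.12e-11) from 3 to 6 h.

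The Hi-C comparison asked how chromatin contacts differed after 1 h in NaCl. In each of the 3 batches short-range contacts took a lower share, and longer-range contacts a higher share, in the NaCl library. Contacts between bins 50 kb to 1 Mb apart made up 56.5% ± 1.54 in untreated and 47.1% ± 1.76 in NaCl libraries (SD, n = 3), out of contacts beyond a single 50 kb bin. The share over 10 Mb was 21.1% ± 1.26 in untreated and 25.7% ± 1.48 in NaCl libraries, and that in between was 22.5% ± 0.325 in untreated and 27.2% ± 0.435 in NaCl libraries. The short-range differences within batches 1, 2 and 3 were -9.58, -8.15 and -10.4 percentage points, and the long-range ones 5.03, 3.69 and 5.25. For each of these 3 shares all NaCl libraries lay on one side of all untreated ones, giving p = 0.1 in the two-sided exact permutation test, the smallest that 3 against 3 libraries allow. The paired exact sign-flip permutation test gave p = 0.25, also the smallest possible. The NaCl library also held more contacts in each batch, 1.34, 1.07 and 1.47 times those of the untreated library in batches 1, 2 and 3 (paired exact sign-flip permutation p = 0.25). The ranges of the groups overlapped, with 65712963 to 133196134 contacts in the untreated and 96728634 to 142395486 in the NaCl libraries (two-sided exact permutation p = 0.5).

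**Figure D3:**
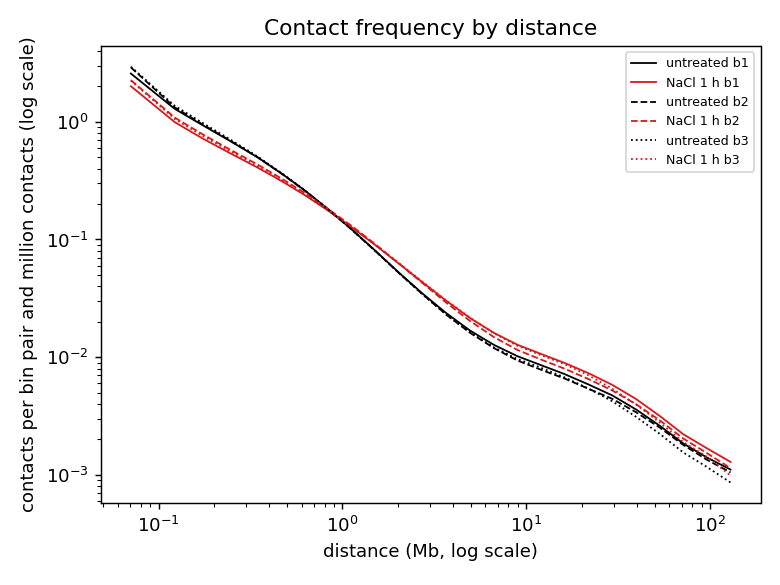
Contacts per pair of 50 kb bins, scaled to the library's total (vertical axis, log scale) against the distance between the bins in Mb (horizontal axis, log scale) for the 3 untreated (black) and 3 NaCl-treated (red) Hi-C libraries, with line style marking the batch. NaCl libraries lie below untreated ones at the shortest distances and above them from 3 to 10 Mb, where the log2 change was 0.34, 0.32 and 0.40 in batches 1, 2 and 3.

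With bins ranked by the mean untreated eigenvector, active (A) and inactive (B) compartments were less segregated in each NaCl library than in any untreated one. Compartment strength, the ratio of contacts within to contacts between the 20% most A-like and 20% most B-like bins, was 4.68 ± 0.319 in untreated and 2.9 ± 0.103 in NaCl libraries (SD, n = 3), with within-batch differences of -1.64, -2.04 and -1.66. The mean difference of -1.78 was -0.617 with bins ranked by the mean NaCl eigenvector and -1.52 with each library ranked by its own. It was -2.93 with 10% and -1.02 with 30% extremes. Contacts between A and B regions went from 0.372 ± 0.0216 to 0.539 ± 0.014 of the level expected for their distance. Those among A regions went from 1.94 ± 0.0018 to 1.61 ± 0.0511. These 3 measures each had an exact permutation p of 0.1. Contacts among B regions were 1.54 ± 0.0374 in untreated and 1.52 ± 0.0805 in NaCl libraries (exact permutation p = 0.8). The share of a bin's contacts within 500 kb was measured on 18 chromosomes only. There the eigenvector correlated with gene density at 0.2 or more in every library. The 20% extremes were drawn over these chromosomes together. This share changed by -6.84 percentage points in the most A-like and -11.7 in the most B-like bins. The difference between them widened in each batch, by 5.2, 4.68 and 4.85 points (exact permutation p = 0.1).

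At the level of 100 kb bins, the deposited first eigenvector was higher (more A-like) in 856 and lower in 6457 of 27092 bins by limma with Benjamini-Hochberg adjustment. With quantile normalization, the split was 4351 higher and 2546 lower, so its direction depended on how the libraries were scaled. The total was 3967 without untreated replicate 2, 4591 without NaCl replicate 2 and 4601 without NaCl replicate 3. The eigenvector changed sign in all 3 batches from A to B in 1683 bins and from B to A in 194, of which 395 and 82 lay on chromosome 7. With quantile normalization these counts were 729 and 890. Among the named regions, the bin over NCAM2 (chromosome 21, 21000001 to 21100000) went from -1.29 to 0.27 SD units and that over RBM26 (chromosome 13, 79300001 to 79400000) from -0.50 to 0.82 SD units. On chromosomes 9, 10 and X the correlation of the eigenvector with gene density was under 0.2 in each of the 10 libraries. On chromosomes 4 and 7 it was above 0.2 in the 3 untreated libraries and below it in some or all of the NaCl libraries. A and B are therefore not assigned with certainty on these 5 chromosomes. The lowest correlation between untreated libraries was -0.97 on X, nearly the same pattern with the sign reversed. The sign there rested on correlations with gene density of only 0.0072, 0.0411 and 0.029 in untreated batches 1, 2 and 3. Between NaCl libraries the lowest was -0.24 on chromosome 4, where the patterns themselves differed. Chromosome X stays in the counts over 27092 bins and in compartment strength, which differed by -1.93 on autosomes alone. The other 4 regions that the naming rule selects lay on these 2 chromosomes, at FRMPD4 (chromosome X, 12000001 to 12100000), at FGF2 and NUDT6 (chromosome 4, 122800001 to 122900000), and at chromosome X, 98900001 to 99000000 and chromosome 4, 101400001 to 101700000. Their changes are not given, because they rest on means over eigenvectors that disagree in sign (X) or in pattern (chromosome 4). On the other 18 chromosomes, where it was at least 0.2 in every library, 747 bins were higher and 5916 lower of 20309, and 1489 and 8577 with the batch as a block. The sign changed in all 3 batches from A to B in 1103 bins and from B to A in 95. With quantile normalization there, 2780 bins were higher and 2314 lower, and 452 and 466 changed sign from A to B and from B to A, so the balance depends on the scaling there too. Without it, the largest decreases lay over RUNX1 (chromosome 21, 34900001 to 36000000, 0.77 to -0.88 SD units), over a region holding BRWD1 and DSCAM (chromosome 21, 39300001 to 41400000, 0.72 to -0.85 SD units) and at chromosome 13, 46900001 to 47800000 (0.75 to -0.76 SD units). The largest increases there were at NCAM2 (chromosome 21, 21000001 to 21300000, -1.14 to 0.012 SD units), over APP and GABPA (chromosome 21, 25700001 to 26000000, -0.94 to -0.0027 SD units) and over RBM26 and NDFIP2 (chromosome 13, 79300001 to 79500000, -0.14 to 0.78 SD units).

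Domain boundaries were weaker after NaCl. The mean log2 insulation score at boundaries called in untreated libraries, where more negative values mean stronger insulation, was -0.74 ± 0.018 in untreated and -0.48 ± 0.013 in NaCl libraries (SD, n = 3, exact permutation p = 0.1). The differences within batches were 0.26, 0.25 and 0.28. Of 3015 boundaries tested with limma, 2073 were weaker and 54 stronger. At boundaries called in NaCl libraries the mean difference was 0.17, against 0.26 at untreated ones, and 1261 of 2525 were weaker and 212 stronger. Calling boundaries separately gave 3027 in untreated and 2535 in NaCl libraries, and 68.5% of the former had one of the latter within 1 bin. The boundaries that weakened most lay on chromosome X, 3950001 to 4000000, with a score higher by 1.28 (SE 0.31, adjusted p = 0.00866) and by 0.94, 0.76 and 2.14 in batches 1, 2 and 3, so that batch 3 puts it first, at RRM1 on chromosome 11, 4100001 to 4150000, from -1.73 to -0.59 (SE 0.043, adjusted p = 7.40e-05), and at TMCO5A on chromosome 15, 37900001 to 37950000, from -1.66 to -0.52 (SE 0.082, adjusted p = 1.39e-04). Those that strengthened most lay at C16orf74, EMC8 and COX4I1 on chromosome 16, 85750001 to 85800000, from -0.96 to -1.41 (SE 0.059, adjusted p = 6.95e-04), at ZPBP on chromosome 7, 50000001 to 50050000, from -0.82 to -1.18 (SE 0.070, adjusted p = 0.00331), and at CXCR2 on chromosome 2, 218100001 to 218150000, from -0.70 to -1.05 (SE 0.034, adjusted p = 2.66e-04).

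Summed into 1 Mb bins, 34598 of 194424 bin pairs within chromosomes had more and 2110 fewer contacts in NaCl libraries by edgeR. Of 2882 tested counts within a single 1 Mb bin, 1631 were lower and 1 was higher. A and B were assigned on the 18 chromosomes by the eigenvectors of the 3 untreated libraries, which are 1 side of this test. A shift from A-A to A-B pairs in NaCl can follow in part from that choice. No assignment from NaCl libraries was run for bin pairs. Pairs of an A and a B bin made up 20305 of the increases and 75 of the decreases. With the distance effect removed, 5322 of 68299 A-B pairs were higher and 434 lower. Of 41368 A-A pairs, 29 were higher and 2323 lower, and of 36710 B-B pairs, 187 were higher and 155 lower. Pairs without an assigned compartment numbered 2087 higher and 866 lower. Scaling changed the split, to 9146 higher and 6636 lower with TMM and to 7625 and 3778 with scaling at each distance, and the batch block gave 64446 and 5805. The total was 16685 without untreated replicate 2, and 21694, 23306 and 16860 without NaCl replicate 1, 2 or 3.

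Genes higher at 1 h were then compared with genes not called, by the Hi-C change at their midpoint. The share of contacts within 500 kb changed by a median log2 of -0.18 at the 1096 genes higher in NaCl and -0.21 at the 15587 genes not called, a difference of 0.026 (permutation test, 100000 resamples, two-sided, p = 3e-05, adjusted p = 1.80e-04 over 6 comparisons). The eigenvector difference between these sets was 0.0161 SD units and did not pass (permutation p = 0.131, adjusted p = 0.193), but on the 18 chromosomes it was 0.0252 with an adjusted p of 0.0251. Neighbouring genes share bins and are not independent replicates. Comparisons that involve genes lower at 1 h are void, because only 73.7% of them could be placed, under the 80% required, against 85.6% of those higher and 80.7% of those not called.

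Single batch 3 libraries covered pretreatment with 500 nM triptolide for 3 h and recovery for 1 h after NaCl, without replicates or a test. Short-range shares were 57.8% in the untreated and 47.4% in the NaCl library of that batch, 55.2% with triptolide and 45.5% with NaCl and triptolide. After recovery the share was 56.7%, and 55.7% after recovery with triptolide. Both recovery values and that of triptolide alone lay within the range of the 3 untreated libraries (54.8 to 57.8%). Compartment strength was 4.56 in the untreated library, 2.9 with NaCl, 4.23 with triptolide and 2.68 with both. It was 4.08 after recovery and 3.52 after recovery with triptolide. These 2 values and that of triptolide alone lay below the untreated range (4.45 to 5.05). The bins were ranked by the mean eigenvector of those same 3 untreated libraries, which can favour them. No other ranking is given here for the single libraries, so the comparison does not decide whether recovery was complete. Boundary insulation was -0.70 with triptolide, -0.48 with NaCl and triptolide, -0.70 after recovery and -0.67 after recovery with triptolide, against -0.76 in the untreated and -0.48 in the NaCl library. All 4 values lay above the range of the 3 untreated libraries (-0.76 to -0.72), in which the boundaries had been called, so this range too may be favoured. The 95% Wilson interval of each short-range share spans under 0.1 percentage points and covers counting error only.

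**Figure D4:**
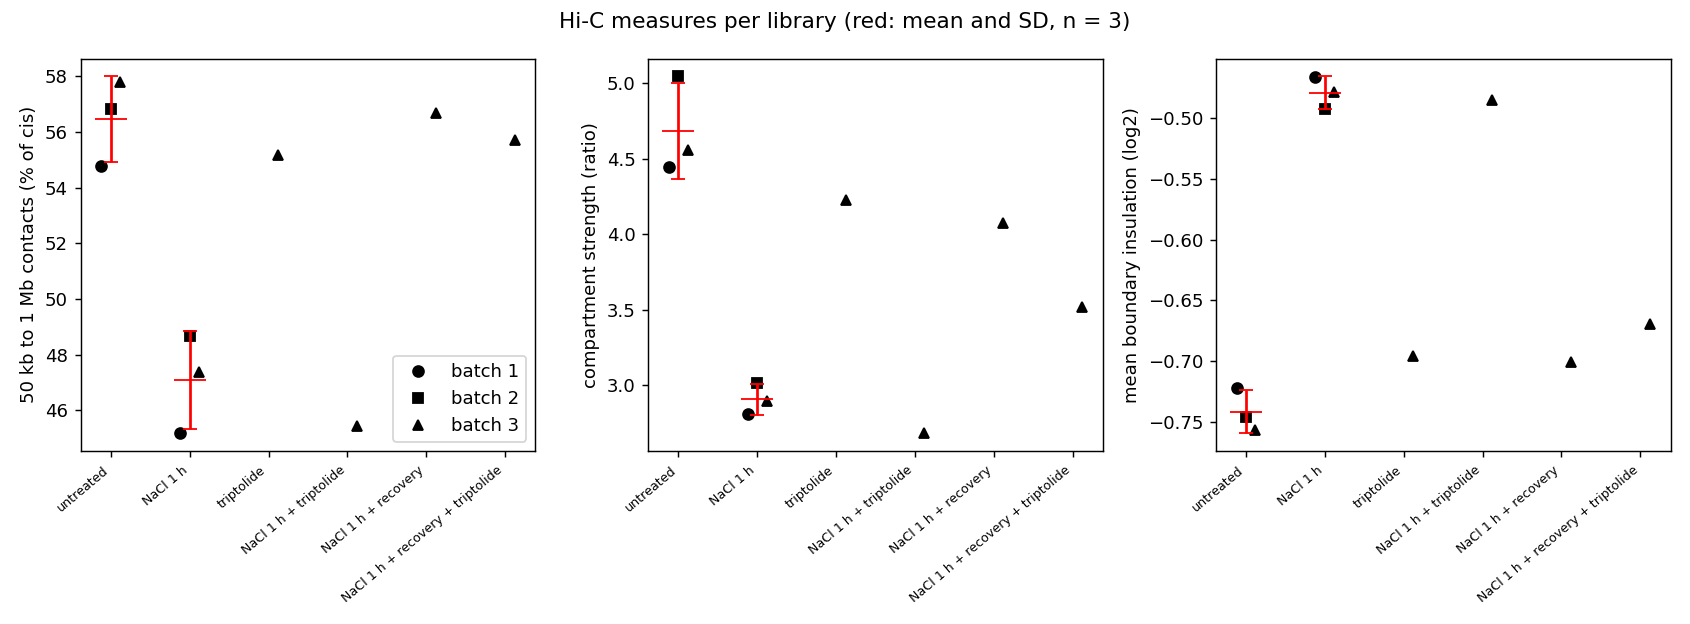
Short-range share of contacts in percent (left), compartment strength as a ratio (middle) and mean log2 insulation at boundaries (right) for each of the 10 Hi-C libraries by condition (horizontal axis), with the marker shape giving the batch and red bars the mean and SD of 3 libraries. In each panel the 3 NaCl libraries lie apart from the 3 untreated ones, and the axes do not start at 0.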

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

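The tests of the short-range share, of insulation and of the splits were chosen only after the results were seen. No group holds 4 or more samples, so no sample was singled out as far from its group.

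Gene lists whose change differed between successive times were picked out by camera with a preset correlation. None passed with an estimated correlation, where adjusted p ran from 0.0917 to 0.837. From 1 to 3 h the median log2 differences were 0.20 for osmoprotective genes (adjusted p = 0.0108), 0.62 for immediate-early genes (adjusted p = 3.97e-08), 0.15 for heat shock genes (adjusted p = 1.62e-05) and 0.14 for cholesterol biosynthesis genes (adjusted p = 0.00295). In the same interval they were 0.15 for cohesin and CTCF machinery genes (adjusted p = 0.0226), 0.10 for ion and volume transport genes (adjusted p = 0.0141), -0.44 for mitochondrially encoded mRNAs (adjusted p = 1.12e-06) and -0.077 for cytosolic ribosomal protein genes (adjusted p = 0.0225). From 3 to 6 h they were 0.54 for osmoprotective genes (adjusted p = 0.0317), -0.53 for immediate-early genes (adjusted p = 0.00265), 0.46 for heat shock genes (adjusted p = 1.13e-07) and 0.43 for cholesterol biosynthesis genes (adjusted p = 0.0124). In that interval they were also 0.24 for RNA polymerase II elongation genes (adjusted p = 0.0108), 0.24 for cytosolic ribosomal protein genes (adjusted p = 3.41e-08) and 0.30 for glycolysis and hypoxia genes (adjusted p = 0.015).

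Named genes whose direction against untreated cells turned between successive times, with a difference that passed edgeR's test, were also picked out. From 1 to 3 h the log2 change of the taurine transporter gene SLC6A6 differed by 1.22 (SE 0.083, adjusted p = 3.01e-08, from -0.27 to 0.95 against untreated), and that of the kinase gene WNK1 by 0.65 (SE 0.090, adjusted p = 5.64e-05, from -0.33 to 0.32 against untreated). From 3 to 6 h the largest differences were those of DDIT4, 1.96 (SE 0.084, adjusted p = 6.12e-11, from -1.72 to 0.25 against untreated), IRF1, 1.44 (SE 0.10, adjusted p = 1.38e-08, from -0.67 to 0.77 against untreated), and CCNT1, 1.42 (SE 0.10, adjusted p = 8.90e-09, from -0.82 to 0.60 against untreated). ANKRD37 differed by 1.15 (SE 0.12, adjusted p = 1.04e-06, from -0.71 to 0.44 against untreated), RPSA by 0.91 (SE 0.11, adjusted p = 5.39e-06, from -0.41 to 0.50 against untreated) and PFKFB3 by 0.58 (SE 0.069, adjusted p = 5.06e-06, from -0.30 to 0.28 against untreated). The luminal genes SPDEF and ESR1 went the other way, by -0.68 (SE 0.083, adjusted p = 6.68e-06, from 0.28 to -0.40 against untreated) and -0.63 (SE 0.076, adjusted p = 5.96e-06, from 0.31 to -0.32 against untreated).

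The lower short-range share of contacts after NaCl was weighed against technical explanations. Sequencing depth does not account for the whole fall, since batch 2, whose NaCl library held 1.07 times the contacts of its untreated one, still changed by -8.15 percentage points. The falls are nonetheless ordered by that ratio (1.07, 1.34 and 1.47 for changes of -8.15, -9.58 and -10.4), so a smaller contribution of depth stays open with 3 batches. More random ligation in NaCl libraries would add most where contacts are rarest, but the log2 change over 50 Mb minus that at 3 to 10 Mb was at most -0.088 over the 3 batches, below 0 in each. This argues only against random ligation as the sole cause. The change over 50 Mb was itself 0.25, 0.17 and 0.27 in batches 1, 2 and 3. A smaller contribution stays open, because another gain at 3 to 10 Mb could hide it and contacts between chromosomes were not available. An effect of NaCl on chromatin folding remains a hypothesis, and effects of the altered salt on fixation or digestion were not tested.

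The weaker insulation after NaCl was weighed against regression to the mean, since boundaries were chosen in untreated libraries. Boundaries chosen in the other batches changed by a mean of 0.26 in the batch left out, close to the 0.26 at untreated boundaries. Boundaries chosen in NaCl libraries, where regression alone would give a value below 0, changed by 0.17. That smaller value leaves open that the choice of boundaries sets part of the size. An effect of NaCl may account for it, and fixation in altered salt was again not tested.

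Of the 10 splits of the 6 Hi-C libraries into 3 and 3, 1 gave as many calls as the real one, namely the real one itself. This held for eigenvector bins with limma (7313, highest other 0), boundaries with limma (2127, highest other 0) and 1 Mb pairs with edgeR (36708, highest other 0). At an unadjusted p under 0.05 the counts were 11626 bins, 2205 boundaries and 67304 pairs for the real split, and at most 1576, 35 and 11446 for the others. With 10 splits the share cannot fall under 0.05. Every other split mixes NaCl and untreated libraries in both groups, so a broad difference between them would widen the spread and lower the counts. Low counts in those splits therefore do not show what libraries without a treatment difference would give. Like the real split, 3 others put the libraries of each batch in different groups, with at most 1265, 8 and 727 at an unadjusted p under 0.05. The remaining 6 part 1 batch and keep the other two together.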

How the results depend on the processing

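Of 185 recomputed values of the main results, 144 kept their side of the threshold, moved by less than the spread between replicates or, for a count, stayed within 1.5 times its total, whatever its balance of higher and lower calls. Of the others, 34 moved further, 4 fell below and 2 rose above the threshold, and 1 reversed. The balance of calls turned at 1 h, at 6 h, from 3 to 6 h and for the eigenvector in the settings given beside those counts, and in no other setting run. Of 2244 values of named genes, 2133 kept their call, 97 lost it, 14 gained one and 0 reversed. The settings on 18 chromosomes (also with the block or quantile normalization), sign changes with quantile normalization, autosomes, NaCl-called boundaries, boundaries called in the other batches, the NaCl eigenvector, compartment pairs under or over 10 Mb apart, eigenvector deciles and gene placement by current symbol were chosen after seeing the data. Unless stated, the cause was not tested. Alternatives for the share of contacts between chromosomes were not run, because the values hold only contacts within chromosomes.

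Requiring a 2-fold change left 778, 2102 and 3621 genes at 1, 3 and 6 h, 1199 from 1 to 3 h and 2135 from 3 to 6 h, by construction. Leaving out 1 library, which leaves a lone sample assumed to vary like the other groups, gave 1386 to 3459, 3542 to 6601 and 8477 to 12068 genes at 1, 3 and 6 h, 2448 to 4812 from 1 to 3 h and 6334 to 9981 from 3 to 6 h. Called lists numbered 0 with an estimated correlation and 18 to 22 with a library left out. The batch as a replicate block gave 3343, 6082 and 11552 genes at 1, 3 and 6 h, and 19 lists. It gave 70251 bin pairs, and 10066 eigenvector bins on 18 chromosomes in place of 6663. Beyond the 3 lists, MSMO1 and CDK1 named above, it changed no other call of a list or named gene, and it moved no other total of calls by over 1.5 times.

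The long-range difference was 6.17 points over 5 Mb and 3.02 over 20 Mb, as the limit itself brings. Compartment strength differed by -2.93 with 10% and -1.02 with 30% extremes, -1.52 with each library's own eigenvector, -0.617 with the NaCl mean eigenvector and -2.51 on 18 chromosomes. Insulation differed by 0.32 with a 250 kb diamond, 0.24 with raw counts and 0.17 at NaCl boundaries. Bin pairs numbered 15782 with TMM and 11403 with scaling at each distance. With a library left out, the differences ran from -10.2 to -8.43 points (short-range), 3.81 to 5.32 points (long-range), -1.93 to -1.70 (strength) and 0.26 to 0.27 (insulation). Counts ran from 3967 to 7633 eigenvector bins, 1913 to 2243 boundaries and 16685 to 36615 bin pairs.

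For the Hi-C change at genes, the comparison of higher with uncalled genes in local contacts kept its call in each alternative. The difference of 0.026 was 0.0266 with current symbols only, 0.0273 with 1 gene per bin and 0.0188 within deciles of the untreated eigenvector. Expression level was not matched. On 18 chromosomes the eigenvector difference for these sets was 0.0252 and passed. Comparisons with genes lower at 1 h are void through placement, and are given only as values. With 1 gene per bin, higher minus lower genes gave 0.00511 (eigenvector) and 0.0108 (local contacts), and lower minus uncalled genes 0.0156, reversed, and 0.0165. Within deciles of the untreated eigenvector, higher minus lower genes gave 0.0259 and 0.0177. In data simulated for the 1 h comparison, 102 of 200 genes changed 1.5-fold were called. Changes of that size can thus be missed there at this depth and spread. The data held more called genes at 1 h (1281 higher, 1593 lower) than the 200 changed in the simulation, so the share missed may differ.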

Other observations

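The zinc finger gene family and the gene spans were looked at only after the results were seen. Of 459 tested genes whose symbol is ZNF and a number, 41 rose and 246 fell at 3 h, with a median log2 fold change of -0.41. None of 10000 random lists of other genes, matched on mean expression, had a median as low (0 of 10000), and the median of their medians was -0.011. At 6 h 85 rose and 236 fell, with a median of -0.35 against -0.094 for the median of the random lists, and again 0 of 10000 lists as low. At 1 h 62 rose and 52 fell, with a median of -0.0006 against 0.024 for the median of the random lists, of which 115 of 10000 were as low. These genes were noticed because ZNF14 and ZNF737 were among the largest decreases at 3 h, and ZNF551 and ZNF608 at 6 h. The random lists describe these libraries and do not replace replicates.

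Among genes past the threshold, 1354 rose and 748 fell at least 2-fold at 3 h. A hypothesis written before its result was seen is that transcripts running on from expressed neighbours may be counted in genes of low expression. Genes under 1 CPM in untreated cells that rose (924) lay a median of 12.2 kb from a gene expressed at 10 CPM or more, against 23.4 kb for the 4047 others, a ratio of 0.522 (permutation p = 5e-05). Only 66.9% of these low genes could be placed, under the 80% required, so the test is void and the explanation stays open. No biological explanation was tested.

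Genes higher at 1 h spanned a median of 25.3 kb and uncalled genes 22.5 kb (permutation p = 0.0331, not adjusted). The span of genes lower at 1 h is not given, because 78% of them had a span, under the 80% required. For the eigenvector change at genes higher at 1 h, permuting calls within deciles of the untreated eigenvector, a test written before its result was seen, gave a permutation p = 0.0967. The unmatched difference had itself not passed (permutation p = 0.131), so this decides nothing.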
